A study of Mus musculus with 16 samples.

How the data were processed

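Genomic DNA from tails of 8 mice of 1 family was hybridised on 16 arrays, 2 per mouse with the dyes exchanged, against DNA of 1 reference male from the same colony. The 16 scanner files and the authors' value table were used. Per the file headers, the arrays were read with an Agilent G2505C scanner and Feature Extraction 10.7.1.1, with probe positions on mm9 (NCBI37). The intensity values of the red and green channels were background-subtracted and dye-normalised with a linear factor per channel, per the file headers. The log10 ratio in the files is red (Cy5) over green (Cy3), per the file headers, and was used only to find the scale of the authors' table. The deposited log2 values in that table were compared with the scanner's ratios on each array. They equal log2 of reference over mouse on all 16 arrays plus a constant of at most 0.0111 per array, so scale and direction were settled from the data; what the constant is for stays unknown. The medians of its columns lay between -0.00493 and 0.0167.

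The dyes in the labels give the direction, and every array was turned so that mouse stands over reference. Low Y and high X values in the dam bear the direction out. Log2 ratios of processed signals were centred on each array's autosomal median, with no loess or quantile step, because many probes of a copy number array can shift one way. Control spots and spots flagged as outliers were left out (109 to 166 flagged spots per array), no spot was saturated, and spots of one probe were averaged. This gave 157732 of 157955 probes. The 2 arrays of a mouse were averaged into 1 value, which cancels a dye effect that both carry. Technical dye swaps were counted as 1 replicate, so n counts mice. The sire and the dam are 1 mouse each and have no replicates.

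Regions were searched in each mouse by interval scoring in the manner of ADM-1, the sum of log2 ratios over the noise times the root of the probe number. The noise was taken from differences between neighbouring probes in the mean of a mouse's 2 arrays, at 0.0415 to 0.0621. On single arrays it was 0.0908 to 0.1195. A region needed a score of 6, at least 3 probes, a mean of at least 0.25 in size, a mean of at least 0.2 with the same sign in each dye orientation, and no gap over 100 kb. Both orientations were required because the labels' design text states that rule. Calls of the same sign sharing a probe were merged. A region counted as absent from both parents when each parent's mean was under 50% of the mean of the calling progeny. The background search used the difference between orientations after removing its mean over the other 7 mice. The rule for each orientation cannot apply to a difference, so that search was looser.

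Per-probe tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment at 0.05. Litter against reference and sire against dam came from 1 fit with sire, dam and progeny means, in which the spread comes from the progeny. Litter against parents used a fit with 2 groups. Region work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and statsmodels 0.14.6, and figures used matplotlib 3.10.9. Transmission was tested per region by two-sided exact binomial tests.

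The search was tested on simulated data with regions planted at 157732 real probe positions. For copy number regions per mouse it found 93.8% of regions of 0.3, 100% of those of 0.6 and 100% of those of 1 on the log2 scale, with 1 other call over 8 mice. The simulated noise was independent between probes and held no brightness trend, so background from dye effects is better read from the dye difference. Effects of the same sign in both orientations cancel in that difference, as copy number does, so it cannot count false calls from them. In limma on 157732 simulated probes, changes of 0.6 were found at 100% for the litter against the reference, 96% against parents, 64% for sire against dam and 89% for 1 mouse against the other 7. Changes of 0.3 were found at 98%, 73%, 10% and 40%.

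Before the data were examined, the following alternatives were fixed: normexp with an offset of 50, loess, the authors' table, only probes well above background, outlier spots kept, a mode centre, each dye orientation alone, other thresholds for score, probe number, mean, gap and merging, robust variances, slide as a random block, and leaving out each mouse. The normexp alternative departed from the one fixed: it used median signals and median local backgrounds in place of means. A minimum of 10 probes was added after seeing the data. The text names the 10 regions of the highest score, up to 10 absent from both parents and up to 5 of exactly 1 parent, and for probe tests the 5 stretches with the most significant probes in each direction; regions met by more than 1 part of the rule are counted under each. The files name no genes, and the gene table given is of another genome build, so the planned test of gene lists was not run and no gene is named.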

Results

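The series measured DNA copy number in 1 mouse family of the C57BL/6JNrs colony by 2-colour comparative genomic hybridisation, in which labelled DNA of a mouse and of a reference compete for the same probes. A sire, a dam and 6 of their progeny (1 sire, 1 dam, n = 6 progeny) were each hybridised against tail DNA of 1 reference male, on 2 arrays with the dyes exchanged, 16 arrays in all. The series belongs to a study of males kept under gamma rays at 1 mGy per day for 400 days, but its title and its design text give different accounts of whether this sire was irradiated, so the sire's exposure was left open. No other family was analysed here, and nothing below compares exposed with unexposed animals. The array was a second screen: it tiled 161987 spots densely over regions that a first array had picked in this same family, so the number of regions found is no genome-wide rate. The number of arrays limits the precision. On every array at least 99.658% of the spots were well above background in both channels. Median spot signals lay between 597.5 and 1995 units over local backgrounds of 45 to 86 units. All signed values below are log2 of mouse over reference; the authors' value table runs the other way, as reference over mouse. Positions are those of the mouse build mm9 given by the files, which name no genes, so regions are named by position alone.

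The region with the highest search score was a gain on chromosome 4, from 101109089 to 101271028 (161.94 kb, 1345 probes), that every mouse of the family carried relative to the reference male, at a pair of levels. The sire had a mean log2 ratio of 0.84 and progeny 4 had 0.86. The dam had 0.48, and the other progeny lay between 0.43 and 0.48. The mean of the litter was 0.52 ± 0.17 (SD, n = 6). The 197 probes within 50 kb outside the region had means between -0.02 and 0.01 in the 8 mice, and each level was seen with both dye orientations: progeny 4 had 0.89 with the mouse in Cy5 and 0.83 with the mouse in Cy3, and progeny 6 had 0.45 and 0.40.

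**Figure D1:**
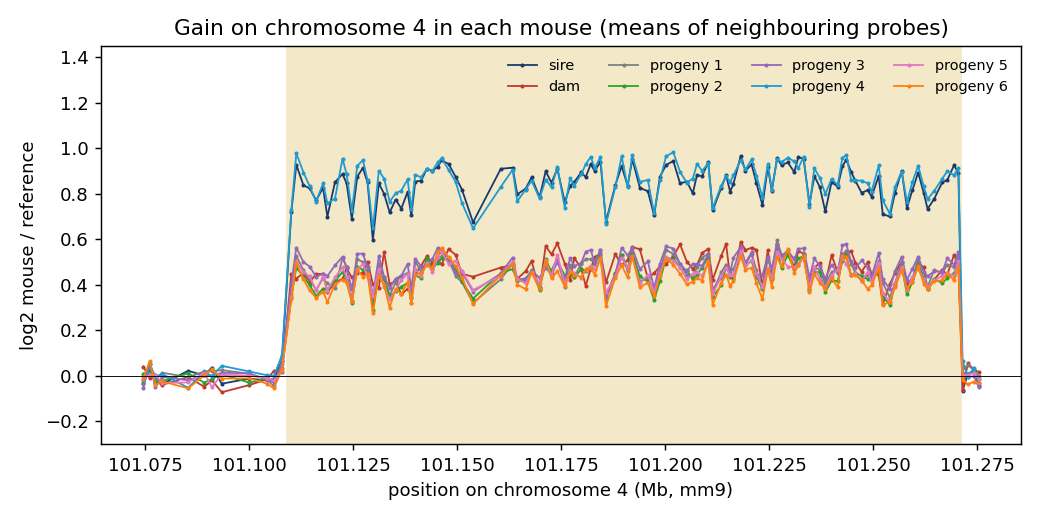
Log2 ratio of mouse over reference (vertical axis) against position on chromosome 4 in Mb on mm9 (horizontal axis), each point the mean of neighbouring probes and each line 1 mouse. The shaded region is the called gain: the sire (mean 0.84) and progeny 4 (0.86) run above the other 6 mice, which lie between 0.43 and 0.48, and all 8 return to 0 at both edges.

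On chromosome 2, sequence from 70079530 to 70086801 (7.272 kb, 70 probes) was bright in the sire and progeny 1, 4 and 6 and nearly dark in the reference and the other 4 mice. The mean log2 ratios were 3.10 in the sire, 2.48 in progeny 1, 3.21 in progeny 4 and 2.36 in progeny 6, against values between 0.01 and 0.06 in the dam and progeny 2, 3 and 5. Median brightness there was 0.567 of the array's median in the sire and 0.054 in the reference. At 11 of the 70 probes the reference was not well above background on any of the 16 arrays, so the ratio is only a lower bound at those probes. The sizes depend on that near-dark signal: over the 35 probes well above background on all arrays the values were 1.57 in the sire, 1.05 in progeny 1, 1.61 in progeny 4 and 0.96 in progeny 6, and with normexp they were 1.489, 1.453, 1.496 and 1.602. Short calls inside this stretch also occurred in the dam and in progeny 2 and 5, and they count as calls of the same merged region.

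On chromosome 3, from 25416456 to 25456288 (39.833 kb, 149 probes), the dam and progeny 5 and 6 had a deep loss in ratio. The other mice did not differ from the reference. Median brightness was 1.06, 1.01 and 1.02 times the array's median in these 3 mice. It was 3.985 in the reference and 3.647 to 4.152 in the other 5 mice. The low ratio therefore does not tell fewer copies in the 3 mice from extra copies in the reference and the others. The means were -1.93 in the dam, -1.88 in progeny 5 and -1.85 in progeny 6, and between 0.00 and 0.03 in size in the other 5 mice. The same 3 mice shared smaller shifts elsewhere: a loss on chromosome 14 from 61797808 to 61820885 (211 probes; -0.26, -0.29 and -0.29) and a gain on chromosome 8 from 102186980 to 102205946 (106 probes; 0.29, 0.30 and 0.30).

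**Figure D2:**
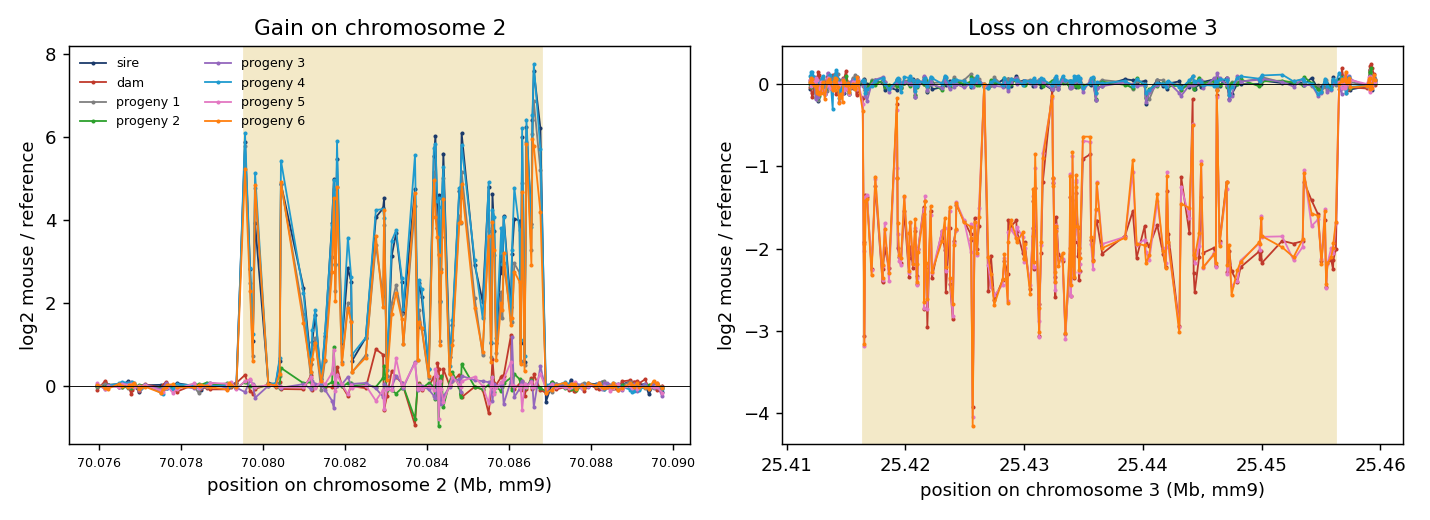
Log2 ratio of mouse over reference (vertical axes) per probe against position in Mb on mm9 (horizontal axes) for the region on chromosome 2 (left) and the one on chromosome 3 (right), each line 1 mouse, with the called region shaded. On chromosome 2 the sire and progeny 1, 4 and 6 rise (means 3.10, 2.48, 3.21 and 2.36), and on chromosome 3 the dam and progeny 5 and 6 fall (means -1.93, -1.88 and -1.85).

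The search for regions in each mouse asks where a mouse differs from the reference in copy number, with the same sign in both dye orientations. It gave 1052 calls over the 8 mice, 297 gains and 755 losses. The sire had 69 calls, the dam 215, and progeny 1 to 6 had 213, 20, 49, 221, 111 and 154. A search on the difference between the dye orientations, where copy number cancels, gave 48 calls in the sire and 48 in the dam. Progeny 1 to 6 had 20, 17, 29, 39, 26 and 28. The background therefore came close to the calls in progeny 2 (17 against 20) and in the sire (48 against 69). It was the looser search, because the rule for each orientation cannot apply to a difference. Without that rule the main search gave 1394 calls. Effects of the same sign in both orientations cancel in the difference and are not counted. A low background count in a mouse therefore does not show that its calls are copy number. Among regions of at least 10 probes the background search gave 0 calls in each of the 8 mice, whereas the sire had 9 such calls, the dam 16 and the progeny 12, 5, 6, 9, 14 and 14. After overlapping calls of the same sign were merged there were 636 regions, of which 610 held 3 to 9 probes and 26 held 10 or more. The small ones lay on dim sequence: their median brightness was 0.352 of the array's median, against 1.27 for the regions of 10 or more probes. Run again with at least 5 probes the search gave 395 calls, with a mean of 0.4 it gave 398, and with normexp background correction 569.

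**Figure D3:**
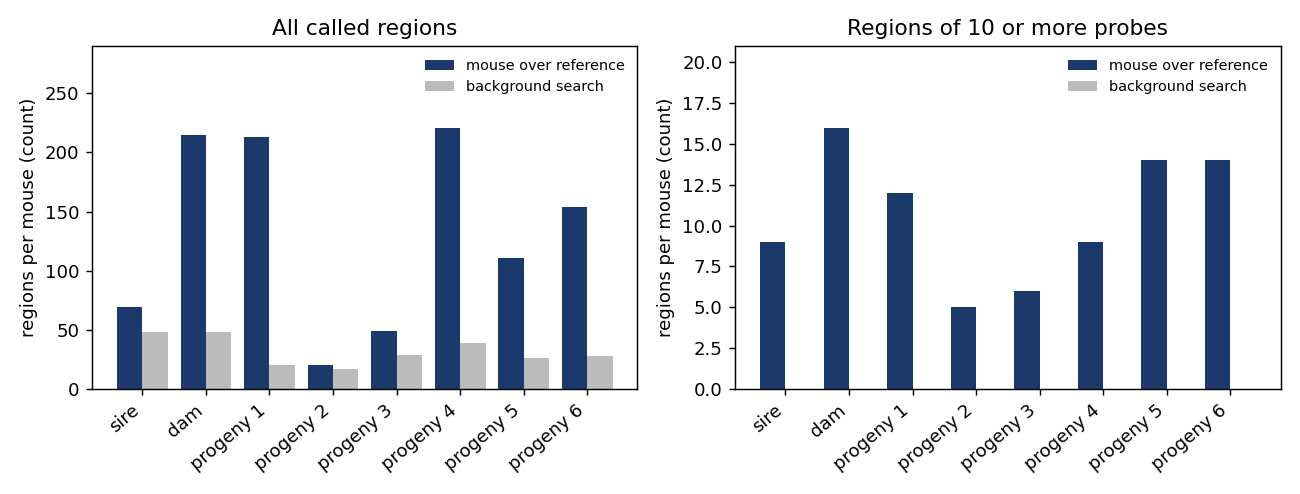
Number of called regions per mouse (vertical axes, counts from 0) for the ratio of mouse over reference (dark bars) and for the background search on the difference between dye orientations (grey bars), for all regions (left) and for those of 10 or more probes (right). The dam has 215 calls and progeny 2 has 20; among regions of 10 or more probes the background search gives 0 in every mouse.

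Probes of the sex chromosomes fitted the labels of both parents, with the reference being male. On the X chromosome (48 probes) the dam's mean was 0.97 ± 0.09 (SD over probes) and the sire's 0.00 ± 0.05. On the Y chromosome (3 probes) the dam's mean was -3.30 ± 2.41 and the sire's -0.03 ± 0.03. The labels give no sex for the progeny. Progeny 5 and 6 had X means of 0.89 and 0.88 and Y means of -2.62 and -2.56. In progeny 1 to 4 X means lay between -0.02 and -0.01 and Y means between -0.05 and 0.03. By these values progeny 5 and 6 read as female and progeny 1 to 4 as male.

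Regions with the same sign and a size of at least 0.25 in all 8 mice ask which differences from the reference male the whole family had; they may still vary in size. There were 3 of them, all gains: the one on chromosome 4, one of 3 probes on chromosome 10 from 97112448 to 97112551 and one of 4 probes on chromosome 13 from 95705972 to 95707908. The short ones had litter means of 0.40 ± 0.04 and 0.45 ± 0.03 (SD, n = 6); they were named after their values were seen. A broad loss on chromosome 14, from 53661805 to 54235460 (573.656 kb, 553 probes), was also called in all 8 mice. It is no single unbroken loss: some stretches inside it lay near 0 in every mouse (-0.07 to -0.00 over 12 neighbouring probes in one of them), and its means average over these. The means differed little between mice, with a litter mean of -0.23 ± 0.02 (SD, n = 6), -0.22 in the sire and -0.22 in the dam. It missed the minimum of 0.25 in 7 mice and is therefore not among the 3. With calls merged only at 50% reciprocal overlap the number was 7, with a minimum mean of 0.4 it was 18, and with at least 5 probes it was 1.

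Following parental regions into the litter asks whether a variant seen in 1 parent reached the progeny. The gain on chromosome 2 from 177149969 to 177350051 (200.083 kb, 160 probes) was 0.45 in the sire and 0.01 in the dam, and 3 of the 6 progeny carried it: 0.44 in progeny 3, 0.44 in progeny 5 and 0.42 in progeny 6, against -0.02 to 0.00 in the others. The size differed by dye orientation: the sire had 0.57 with the mouse in Cy5 and 0.33 in Cy3, and progeny 6 had 0.58 and 0.26, while the mice without the call had 0.09 to 0.16 and -0.19 to -0.11. A loss on chromosome 4 from 118822628 to 118823872 (10 probes) was -0.76 in the sire and -0.12 in the dam, and 4 progeny carried it at -0.60 to -0.73. The loss on chromosome 3 and the shifts on chromosomes 8 and 14 were each seen in the dam and in progeny 5 and 6. These are the 3 mice with the high X and low Y means given above, so these regions cannot be read simply as maternal variants passed on. Of the 260 regions called in exactly 1 parent, 201 were the dam's, 41 of them carried by exactly progeny 5 and 6, and 59 the sire's. Two-sided exact binomial tests of equal transmission with Benjamini-Hochberg adjustment gave 0 of 260 (lowest adjusted p = 0.0829), with 98 at an unadjusted p under 0.05. With 6 progeny the smallest p is 0.0312, so at least 163 regions would have had to reach it before any could pass, and the 0 says little about transmission. In all, 80 of the dam's regions (39.8%) and 16 of the sire's (27.1%) were carried by 0 progeny, where equal transmission gives 1.56%. Among those of 10 or more probes the numbers were 1 of 12 and 0 of 2. The 1.56% holds only where a call is a copy number variant, which was not shown for the small regions on dim sequence.

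**Figure D4:**
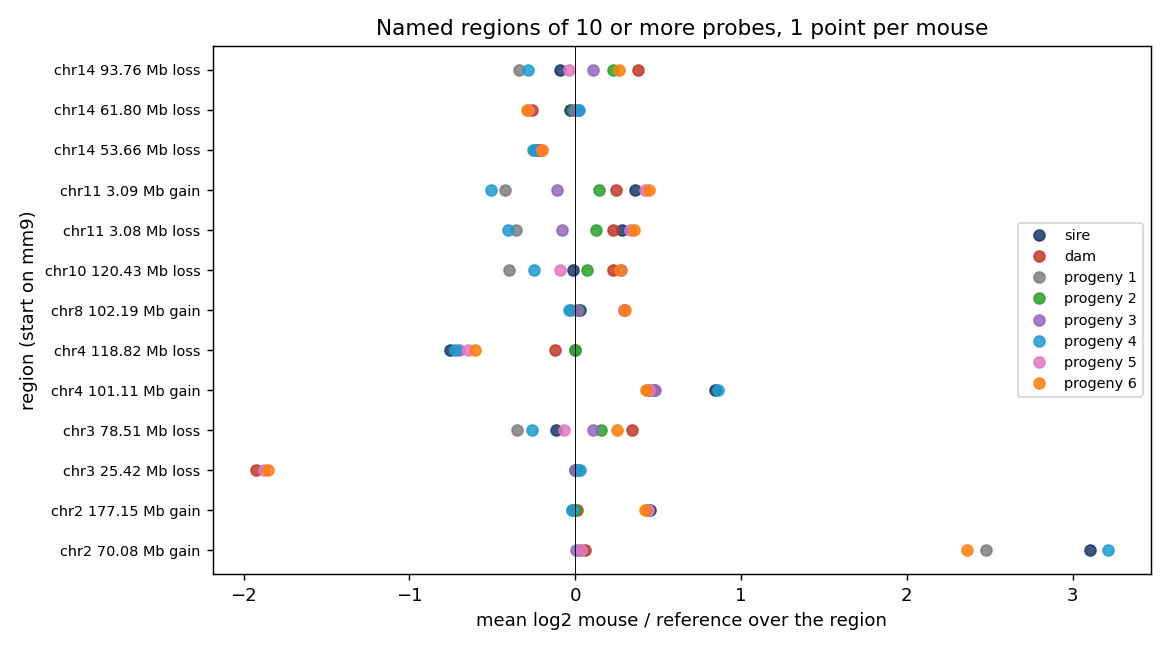
Mean log2 ratio of mouse over reference (horizontal axis) in each named region of 10 or more probes (vertical axis, by chromosome and start in Mb on mm9), 1 point per mouse. The sire and progeny 1, 4 and 6 stand at 2.36 to 3.21 on chromosome 2, and the dam and progeny 5 and 6 at -1.85 to -1.93 on chromosome 3.

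Regions called in progeny but absent from both parents are where a copy number change arising between the generations would show on these arrays. A parent with a value of the opposite sign also counts as absent. There were 271 such merged regions, and 5 of them had 10 or more probes. The largest by score lay on chromosome 11 from 3084399 to 3099912 (15.514 kb, 72 probes): progeny 1 and 4 had -0.36 and -0.40, whereas the sire had 0.28, the dam 0.23, progeny 5 had 0.33 and progeny 6 had 0.35. The size differed by dye orientation over this stretch: with the mouse in Cy5 and in Cy3 progeny 1 had -0.14 and -0.58, progeny 4 -0.26 and -0.55, the sire 0.44 and 0.13, and the dam 0.38 and 0.07. The stretch was bright, at 10.591 times the array's median in the reference and 8.492 to 13.954 times in the 8 mice. Gains were called inside it in the sire, the dam and progeny 5 and 6. Each call met the rule only over its own part of the merged region: over the whole gain from 3090220 to 3099912 the Cy3 means were 0.18 in the sire, 0.06 in the dam and 0.18 in progeny 5, under the minimum of 0.2, as was the Cy5 mean of progeny 1 over the whole loss. Of the 10 named, 9 were losses called in progeny 1, 4 or both, with 1 of these also called in progeny 5. On chromosomes 3 (78511690 to 78512574, 12 probes) and 14 (93761289 to 93761796, 10 probes) progeny 1 and 4 had -0.35 and -0.26, and -0.34 and -0.29. The dam had 0.34 and 0.38 there and the sire -0.12 and -0.09. The other progeny were graded between these: progeny 6, 2, 3 and 5 had 0.25, 0.16, 0.11 and -0.07, and 0.26, 0.23, 0.11 and -0.04. The 8 mice stood in the same order in both regions, and a gain was also called over the same probes of each. In other named losses the sire lay just under the limit for absence, with -0.17 on chromosome 3 (41721396 to 41722312; progeny 1 and 4 had -0.43 and -0.26) and -0.25 on chromosome 11 (77143297 to 77143938; -0.53 and -0.52), so absence there rests on that limit. A loss of 3 probes on chromosome 7 from 18816858 to 18817241 was called in progeny 5 (-0.90) and 6 (-1.12), with 0.08 in the sire and -0.10 in the dam. Progeny 5 and 6 were alone on slide 4 and are the only progeny that read as female. An effect of slide or of sex cannot be told apart from this loss. The dam's median brightness there was 0.313, near that of progeny 5 and 6 (0.28 and 0.265), against 0.456 to 0.711 in the sire and the other progeny. The count of 271 fell to 163 with loess normalisation, 97 with normexp, 70 with at least 5 probes and 52 with a mean of 0.4. The median brightness of these regions was 0.346 of the array's median.

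Testing each probe for the litter as a whole against the reference asks which sequences differ between this litter and the reference male. The gain on chromosome 4 held the most higher probes, 1316 of the 1543 probes of its stretch, with a mean log2 ratio of 0.53 and a mean SE of 0.05. The broad loss on chromosome 14 held the most lower probes, 430 of 553, with a mean of -0.29 and a mean SE of 0.02. Next came losses on chromosome 6 from 123285856 to 123306860 (43 probes, mean -0.12), chromosome 14 from 53364126 to 53532352 (25 probes, mean -0.28), and chromosomes 5 and 11 (24 probes each, means -0.14 and -0.10). No other stretch held more than 9 higher probes. In all, limma gave 11717 of 157732 probes at an adjusted p under 0.05, 2556 higher and 9161 lower, and 15.36% of them lay in regions of 10 or more probes. Their median size was only 0.11, and 4663 were under 0.1. The count was 6698 with normexp, and without progeny 1, 3 or 4 it was 7480, 6656 or 7765. From arrays of a single dye orientation it was 74759 (Cy5) or 74810 (Cy3). The reference is 1 animal, and its own spread is left out.

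The comparison of the litter with its parents asks whether the progeny as a group moved away from both. No probe passed in limma (0 of 157732; lowest adjusted p = 0.0584), with 28064 at an unadjusted p under 0.05. Without the sire, 71 probes passed, and on the Cy5 arrays alone 1592. Both parents lay on slide 1 and the progeny on the other 3 slides; with slide as a random block 1 probe passed.

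Between sire and dam 13 probes passed in limma, 11 higher in the sire and 2 lower, each a single probe in its stretch. The largest difference was on chromosome 12 from 102151090 to 102151135: the sire had 0.01 and the dam -1.87 (adjusted p = 0.00241 from limma, which takes each parent to vary like the progeny). With the mouse in Cy5 this probe differed by -0.08 and with the mouse in Cy3 by 3.84. Of the 13 probes, 1 differed by at least 0.2 with the same sign in both orientations. Without progeny 4 the count was 846 and without progeny 2 it was 8, and with outlier spots kept it was 83. The large regions above, such as those on chromosomes 2 and 3, gave 0 of the 13. The spread in this test comes from the litter and so includes variants that segregate there.

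Setting each mouse against the other 7 asks for sequence private to 1 animal. In limma 62 probes passed over the 8 tests: 49 in the dam, 2 in the sire and 2, 0, 2, 4, 2 and 1 in progeny 1 to 6. The largest private values in the litter were a gain of 1.77 at 1 probe on chromosome 13 from 90455407 to 90455465 in progeny 1 (adjusted p = 7.47e-07, limma) and a loss of -1.47 at 1 probe on chromosome 17 from 87922588 to 87922638 in progeny 5 (adjusted p = 2.85e-06, limma). Each came from a single array: the values were 3.55 with the mouse in Cy5 against -0.01 in Cy3, and -2.97 against 0.04. In the dam, probes higher than in the other mice passed in the main setting but not with loess or normexp, where only lower ones passed. Of the 11 private probes of progeny, 1 reached 0.2 with the same sign in both orientations, and of the dam's 49, 25 did. The count was 323 with robust variance estimation, 251 with outlier spots kept and 26 with normexp.

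Over all probes the correlation between the dye-swapped arrays of 1 mouse, after the signs were turned, ranged from -0.31 in progeny 2 to 0.26 in progeny 6. Arrays of the same orientation from different mice correlated at 0.29 to 0.76. Over the 2856 probes in regions of 10 or more probes the correlation within a mouse was 0.73 to 0.95, but a call already required the same sign in both orientations, so the calling rule sets part of that value. These are correlations across probes, which are not independent replicates.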

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

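Tests of the dye effect and of the chromosome 4 steps were chosen after the results were seen; those of loess and of the whole-array component were written before.

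Among 26 sets of values over the 6 progeny, 1 sample stood far from the others: progeny 4 on the chromosome 4 gain (101109089 to 101271028), at 0.8607 against 0.43 to 0.48 in the other progeny. Chance alone would give about 1.3 such flags in 26 sets. On the linear scale the ratio was 1.82 in progeny 4 and 1.79 in the sire, and 1.35 to 1.40 in the other 6 mice. In units of the median excess over the reference this is 2.13 and 2.07 against 0.902 to 1.04, so the mice fall near 1 and 2 steps. A single-array effect is argued against by both dye orientations giving the higher level in progeny 4. If both extra steps of the sire lay on 1 chromosome and the dam's single step on 1 of hers, progeny with 0 or 3 steps would make up every second animal, and 6 progeny without any would have a probability of 0.0156. A sire with 1 extra step on each chromosome gives progeny of 1 or 2 steps with equal chance, and the 5 to 1 division has an exact binomial p of 0.219. Inheritance of that kind may account for the level of progeny 4, as a hypothesis drawn from the same data. Whether the reference male lacks copies or the family gained them was not tested.

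The 610 merged regions of 3 to 9 probes are the second pattern. The dye effect of single arrays does not account for most calls of this size over the 8 mice, since the search on the dye difference gave 26.4% as many (255 against 967). It stays open in progeny 2 (17 against 15), the sire (48 against 60) and progeny 3 (29 against 43). A trend of the ratio with brightness may contribute: after loess 69.0% of the number remained, a value between the bounds set in advance. Differences between mice that run over the whole array may contribute too. The per-mouse values of 39.2% of these regions tracked the first component of probes outside every region, which also falls between the bounds. Unrelated values reach the limit in 5% of cases, but that is no chance level for regions picked because a mouse deviates. That component held 37.06% of the variance and set the dam (0.82) against progeny 4 (-0.41), progeny 3 (-0.29) and progeny 1 (-0.23). A region shifted in the dam alone therefore tracks it too, so the share cannot decide for an effect over the whole array. These explanations stay open, and no biological one was tested.

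The 271 regions absent from both parents are the third. Of them, 1.85% had 10 or more probes, against 4.09% of all merged regions. The whole-array component was tracked by 32.8%, and by 0 of the 5 with 10 or more probes, whose correlations with it, at 0.449 to 0.675, lay below the limit but had the same sign. The rule of absence itself sets the dam apart from the calling progeny, so part of that share can follow from the rule. The component may account for part of these regions of either size. All mice stood in the same order on chromosomes 3 (78511690) and 14 (93761289). The dam was highest (0.34 and 0.38) and progeny 1 lowest (-0.35 and -0.34). Independent new copy number changes or independently segregating alleles on separate chromosomes have no reason to share an order over all mice. The order therefore argues against them in these regions. The other regions of this set with 10 or more probes had other orders. In those and in the smaller regions, new changes and segregating alleles on either side of the reference remain possible and were not tested. No other family was analysed here.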

How the results depend on the processing

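The alternative of at least 10 probes was chosen after the data were seen. Each setting other than the merging rule ran the search again, and an interval can lengthen to reach a minimum of probes. The 14 absent regions with at least 10 probes are therefore not the 5 of that size in the main setting. Under the following settings counts moved by over 1.5 times or from 0, or other values moved by more than their spread, and where no reason is given the cause was not tested. With normexp there were 569 calls over the 8 mice (1052 in the main setting), 97 regions absent from both parents (271), 6698 probes of the litter against the reference (11717), 26 of each mouse against the other 7 (62) and 130 regions of exactly 1 parent (260 in the main setting); the dam's X mean was 0.92 (0.97) and the median dye-swap correlation turned to -0.12. With loess 163 regions were absent from both parents, 32 probes set 1 mouse apart and the X mean was 0.93. With the mouse in Cy5 only, the numbers were 1788 calls, 492 absent regions, 74759 probes against the reference, 1 for sire against dam, 1592 against parents and 13 for each mouse. With the mouse in Cy3 only, they were 74810, 26, 1 and 476 for the reference, sire against dam, parents and regions of 1 parent; a single orientation keeps the dye effect. With at least 5 probes there were 395 calls, 70 absent and 1 shared region; with a mean of 0.4, 398, 52 and 18; with at least 10 probes, 132, 14 and 1; with 50% reciprocal overlap, 7 shared. Outlier spots kept gave 83 probes for sire against dam and 251 for each mouse, and robust variances 323 for each mouse. For litter against parents, where the main count was 0, the probes above background, the mode centre and the slide block gave 1 each. Leaving out 1 mouse gave 6656 to 9357 probes against the reference, 8 to 846 for sire against dam and 0 to 71 against parents. The score minimum of 5 changed nothing, because the minimum mean already forces higher scores. Mean values of the 19 named regions stayed within 1 SD of the litter in 150 of 151 cases, the exception being a loss of 3 dim probes on chromosome 4 under normexp (-0.87 to -0.17), and none turned sign. That SD is wide where mice differ, and 7 of the 151 moved by over 1.5 times. On chromosome 2 (70079530) the mean over calling mice fell from 1.61 to 0.87 with normexp and 0.75 with probes well above background. The dam and progeny 2 and 5, with only short calls and means near 0 there, are among those calling mice. On chromosome 11 the loss (3084399) went from -0.38 to -0.20 in Cy5, and the gain (3090220) from 0.37 to 0.58 in Cy5 and 0.16 in Cy3. A loss on chromosome 19 (52454049) went from -0.49 to -0.32 with normexp. No paired analysis was possible because all progeny share the same sire and the same dam. Where signal is near background a ratio is only a bound.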

Other observations

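All tests in this part were chosen after the results were seen.

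A set of regions moved together in the dam and progeny 5 and 6. Of the merged regions, 40 were called in exactly these 3 mice, 31 losses and 9 gains on 17 autosomes, and the next most frequent of the 56 sets of 3 mice held 9. They are also the 3 mice with the highest X chromosome means. Independent transmission of maternal variants is argued against. Of the 201 regions called in the dam and not in the sire, 20.4% were carried by exactly progeny 5 and 6 (41 regions; 95% exact interval 15.1% to 26.6%), where it gives 1.56%. Regions of one chromosome can pass on together and the pair was picked from the data, so 1 region per autosome, the one with the most probes, was also counted: 9 of 19 were carried by exactly this pair (exact binomial p times the 64 possible sets = 2.85e-10). The wording of this test was changed after the share was known. Progeny 2 and 6 carried 37 of the 201 by their values, though 4 regions were called in exactly the dam and these 2. With 1 region per autosome, 5 of 19 were carried by exactly progeny 2 and 6, so that pair also showed an excess. Its larger regions had graded values. On chromosome 1 (23057475) the dam had 0.34, progeny 6, 2, 3 and 5 had 0.21, 0.16, 0.07 and -0.09, and the sire had -0.15. Carrying there depends on where the rule of the nearer parent cuts the grade, so the excess of that pair may be another pattern than that of progeny 5 and 6. On the chromosome 3 loss median brightness was 3.985 times the array's median in the reference, against 1.06 in the dam, 1.01 in progeny 5 and 1.02 in progeny 6. The 3 mice share the sex chromosome values of a female against the male reference, with X means of 0.97, 0.89 and 0.88. The grouping thus follows sex as read from the X and Y values, while what makes their regions move together is not settled. Further copies of such sequence on the sex chromosomes were not tested apart from the pattern itself. Technical differences between mice were not tested for this set. Progeny 5 and 6 shared slide 4 with no other mouse, while the dam was on slide 1. The sire lay on slide 1 too and was called in none of the 40 regions, so slide alone does not give this grouping.

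Setting other choices of 2 mice against the remaining 6, in place of the parents, gave up to 1254 probes, for the sire with progeny 4. These are the mice with the higher level of the chromosome 4 gain, a structure of the samples that this split follows. The parents' own count was 0, which no choice can fall below, so the comparison says nothing about chance.

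Some sequence was nearly dark in the reference and in all 8 mice. On chromosome 4 from 30872267 to 30873464 (11 probes) and from 30873575 to 30874965 (16 probes) median brightness in the reference was 0.016 and 0.0107 of the array's median, and no mouse exceeded 0.0275. Over the array 2.89% of probes were under 0.15 in the reference, and these were the only runs of 10 or more. A ratio cannot show a deletion that the reference shares.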
